A study of Mus musculus with 6 samples.

How the data were processed

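Libraries were made with a droplet kit that reads the 3' ends of transcripts (10x 3' v3) from suspension and adherent cells of cultured fetal mouse lung, 6 libraries in all. Per the submitters' processing notes the reads were handled with bcl2fastq, Cell Ranger and STARsolo on the mm10 genome. The versions of these tools and of the annotation are not given in the sources used here. The deposited tables hold read counts per gene for each whole library, with 31053 Ensembl gene identifiers, 4 summary lines and separate counts for reads on either strand, on the sense strand and on the antisense strand of a gene. They have no cell axis, are not corrected for molecular identifiers, and may include reads from droplets without a cell. The sense column had the larger total in every library and was used. Symbols and coordinates came from GENCODE M21 (GRCm38, the same assembly as mm10), which held 30934 of the identifiers. Where 28 symbols were shared by several identifiers, the one with the most counts kept the symbol.

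Genes with low counts were filtered with filterByExpr of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), which left 14912 of the 22019 genes with any count, and libraries were scaled by TMM. The count totals of the libraries lay between 36451255 and 57784974. CPM values are on the TMM scale. The ± values after log2 ratios and slopes are approximate standard errors, the absolute log2 value divided by the square root of the test's F value. The fractions were compared with a quasi-likelihood test of suspension against adherent libraries (4 residual degrees of freedom). A slope per day common to both fractions was tested with 3 residual degrees of freedom, and the slopes of each fraction and their difference with 2. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. The 3 days serve as the libraries of a fraction, since no fraction was sampled more than 1 time on a day. The labels give both fractions of a day a shared day, so a fit with the day as a block was run as an alternative. Deviations from the fraction mean correlated across genes at 0.318, 0.095 and 0.253 for libraries of the same day and between -0.285 and 0.022 for those of different days, where genes are not independent replicates.

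Gene lists (36, with 502 genes, of which 1 was missing from the tables) covered cell types of the lung and blood, pathways and culture responses, and 12 of them were primary. Lists with at least 3 tested genes were compared with the other genes by limma's camera with a preset correlation of 0.01, and again with an estimated correlation. Limma's fry tested whether the genes of a list moved on balance in 1 direction. The share of counts taken by 10 lists was compared with an exact two-sided permutation test. The lists, the comparisons, the alternatives and the rule for named genes were set before the data were examined, except that list tests on the slopes and on their difference were added afterwards. The rule named, for the fraction contrast and the common trend, the 6 genes with the highest and the 6 with the lowest log2 value past the threshold. These needed a mean of at least 20 CPM, a symbol that was not a Gm or Rik number and the same direction in all libraries of a fraction or in both fractions. It added the 2 members of each primary list past the threshold with the highest mean CPM, or the member with the highest CPM where none passed, and always Cdh5, Pecam1, Ptprc, Runx1, Gfi1, Kit and Cd34. For the slope difference it named the 3 genes with the lowest p in each direction, of which 1 is not reported here. Other genes named as examples were chosen after their values were seen, mostly as called members of a list with high CPM.

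A value against 0 counts in a fraction is given as a bound at 3 counts per library, and a ratio against 1 to 3 counts with a 95% counting interval. The pipeline was tested on simulated data, with counts of the same depth and 200 changed genes. For the fraction contrast it recovered 23.9%, 82.1% and 97% of genes with true log2 ratios of 1, 2 and 4, with 6 false calls among 141. For the common trend it recovered 29.9%, 82.1% and 93.9% of slopes of 0.5, 1 and 2, with 12 false calls among 149. For the slope difference it recovered 4.5%, 58.2% and 90.9%, with 18 false calls among 120, and for the adherent slope 17.9%, 74.6% and 100%, with 13 false calls among 141. False calls were thus above the nominal 5% in the last 3 of these tests. The 200 changed genes are far fewer than the 56.8% of genes called between the real fractions. The shares recovered and the false calls therefore need not carry over to the real data.

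Alternatives were reads on either strand, scaling with DESeq2's size factors, DESeq2 1.42.0 with its Wald test, no filter on low counts, a filter of at least 10 CPM in 3 libraries, counts thinned to the smallest library, globin and mitochondrial genes left out, the day as a block (also with thinned counts), a test against a 2-fold difference, day 6 against day 4 in place of a slope, and each library left out in turn. None of the scaling alternatives moved the median log2 ratio of all genes by more than 0.1. No library was left out of the reported values. In the slope fits, leaving out a library lowers the 2 residual degrees of freedom, and a fraction cut to 2 libraries is fitted without residual. A changed count there need not mean that a slope rests on the library left out.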

Results

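Messenger RNA was measured in cells that were taken from the lungs of C57BL6 mouse fetuses at E17, frozen, thawed and cultured on a thin layer of Matrigel, a basement membrane extract. The medium was one for haematopoietic stem and progenitor cells and held thrombopoietin, IL6, stem cell factor, FGF, VEGF and Flt3 ligand. The wells were washed on day 3, and on days 4, 5 and 6 the cells floating in the medium (suspension) and the cells attached to the plate (adherent) were collected separately. Adherent cells were detached with an enzyme and sorted for live cells carrying VE-cadherin, an endothelial adhesion protein, so that the fractions differ in handling as well as in attachment. There were 6 droplet libraries, 3 per fraction, with 1 library for each fraction on each day. The gene counts of the suspension libraries of days 4, 5 and 6 summed to 43805361, 44199524 and 57784974, and those of the adherent libraries to 38885531, 36451255 and 40882433. A level that gave 3 counts in a library corresponded to between 0.0594 and 0.0756 CPM, a gene's count scaled to a common library total with TMM factors. The values are sums over all droplets of a library, so they give the make-up of each library and not that of its cells. Reads rather than molecules were counted, so intervals and floors cover counting error only. The labels do not say whether the days came from separate cultures, so p-values measure only the spread between these libraries.

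The contrast of the fractions asked how floating cells differed from the attached, VE-cadherin sorted cells they were cultured with, in a study whose title concerns the formation of blood cells from fetal lung. Endothelial and connective tissue genes were far lower in suspension, and most listed genes of neutrophils, macrophages and red cells were higher there. Of 10 genes of megakaryocytes, the platelet precursors, 5 were higher. Of 25 tested genes of the endothelial list, 23 were lower and 1 was higher in suspension by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the counts adjusted over the list alone were again 23 and 1. Their median log2 ratio was -6.83, also with low-count genes set to their bound (camera adjusted p = 7.29e-09, but adjusted p = 0.535 with an estimated correlation). Emcn (endomucin, ENSMUSG00000054690, mm10 chromosome 3, 137341067 to 137432185) had 1 count in the suspension libraries together and a mean of 130.0 ± 67.1 CPM (SD, n = 3) in the adherent ones. That is a ratio of 17390 in favour of adherent cells, with a counting interval from 3122 to 687000. Gpihbp1, which anchors lipoprotein lipase to capillary walls, had 2 counts in suspension and 147 ± 73.3 CPM (SD, n = 3) in adherent cells, a ratio of 9811 (2716 to 81010). Cldn5, a tight junction protein of endothelium, had a log2 ratio of -12.51 ± 0.79 (SE) and Ramp2 and Esam had ratios of -8.34 ± 0.64 and -8.12 ± 0.70. Pecam1 (CD31) was lower by the same test, with 3.69 ± 0.840 CPM in suspension and 97.1 ± 52.7 in adherent cells (SD, n = 3). Cdh5 encodes VE-cadherin, the protein used for the sort, so its log2 ratio of -9.39 ± 0.64 is not counted as a result. With no unsorted adherent library it cannot show how pure the sort was either. Cd93, a receptor also found on monocytes, was the listed gene that was higher in suspension, at 309 ± 29.1 against 155 ± 37.1 CPM (SD, n = 3).

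Genes of connective tissue moved with the endothelial genes. All 15 fibroblast genes were lower in suspension (15 adjusted over the list alone, median log2 ratio -5.08, camera adjusted p = 1.48e-05, adjusted p = 0.535 with an estimated correlation). Fn1 (fibronectin) had a mean of 109 ± 52.4 CPM in suspension and 827 ± 107 in adherent cells, and Col1a2 (a chain of type I collagen) 17.2 ± 11.3 and 705 ± 133 (SD, n = 3). Of 11 pericyte and smooth muscle genes 10 were lower (10 adjusted over the list alone, median -5.02, camera adjusted p = 0.00100, adjusted p = 0.535 with an estimated correlation), among them Acta2 at -5.02. Of 12 basement membrane genes 11 were lower (12 adjusted over the list alone, median -5.16, camera adjusted p = 2.81e-05, adjusted p = 0.535 with an estimated correlation), among them Col4a1 at -5.96. Among 19 epithelial genes 9 were lower and 3 higher (9 and 3 adjusted over the list alone, median -3.10, camera adjusted p = 0.0659). The number lower was 14 without the suspension library of day 4 and 3 without that of day 5. Krt19, a keratin of simple epithelia, was at -3.75 ± 0.99 log2 (adjusted p = 0.0181), but its adjusted p was 0.0720 without the suspension library of day 5. The 3 that were higher were Napsa at 2.85 ± 0.18, Abca3 at 0.70 ± 0.15 and Hopx at 0.45 ± 0.10, which are known for surfactant protein processing, surfactant lipid transport and transcriptional control in alveolar cells. Napsa held at 121, 125 and 120 CPM in suspension on days 4, 5 and 6, while Krt19 fell from 11.4 to 0.77. A higher Napsa therefore does not by itself show alveolar cells in suspension. Adherent libraries thus held counts of fibroblast and epithelial genes after a sort for VE-cadherin.

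Genes of neutrophils and macrophages were mostly higher in suspension, with the larger ratios for those of neutrophils. All 19 neutrophil and granulocyte precursor genes were higher by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (19 adjusted over the list alone, median log2 ratio 5.75, camera adjusted p = 1.21e-06, adjusted p = 0.535 with an estimated correlation). S100a9 (ENSMUSG00000056071, mm10 chromosome 3, 90692632 to 90695721), a calcium-binding protein abundant in neutrophils, was at 11244, 14534 and 37215 CPM in suspension on days 4, 5 and 6 and at 99.7, 351 and 496 CPM in adherent cells. Its partner S100a8 was at 6.05 ± 0.82 log2 (adjusted p = 0.00159). The granule protein genes Ltf, Ngp and Camp were 124, 116 and 88.0 times as high in suspension, the cystatin gene Stfa2 86.0 times and Retnlg 125 times. For Retnlg the adjusted p of 0.0158 became 0.0650 without the adherent library of day 5. Of 23 monocyte and macrophage genes 20 were higher (21 adjusted over the list alone, 1.86 in the median, camera adjusted p = 2.41e-06, adjusted p = 0.545 with an estimated correlation). All 23 had log2 ratios above 0. Lyz2 (lysozyme, ENSMUSG00000069516, mm10 chromosome 10, 117277331 to 117282321) was at 13720 ± 584 CPM in suspension and 2632 ± 1382 in adherent cells, and Spp1 (osteopontin) at 10920 ± 2083 and 4199 ± 1117 (SD, n = 3). Lysosome genes followed, with 14 of 16 higher (14 adjusted over the list alone, median 1.31, camera adjusted p = 0.000115, adjusted p = 0.549 with an estimated correlation). Of 8 listed eosinophil genes only Ear2, Ear6 and Siglecf were tested. All 3 were higher (3 adjusted over the list alone, camera adjusted p = 0.0369, adjusted p = 0.535 with an estimated correlation), with Ear2 at 4.78 log2, and DESeq2 called 6. So few genes do not by themselves show eosinophils in suspension.

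Of 17 erythroid genes 16 were higher in suspension and 1, the water channel gene Aqp1, was lower (16 and 1 adjusted over the list alone). Their median was 5.14, or 5.13 with low-count genes at their bound (camera adjusted p = 8.71e-06, adjusted p = 0.535 with an estimated correlation). With a filter of at least 10 CPM in 3 libraries, which tests fewer genes, 2 erythroid genes were higher and 0 lower. Aqp1, at -1.92 log2, did not pass without the suspension library of day 4, 5 or 6 or the adherent library of day 5 or 6, each of which left 0 genes lower. The adult globin genes Hbb-bs and Hbb-bt were at low levels in suspension, 65.8 ± 50.8 and 35.3 ± 19.98 CPM, against 0.216 ± 0.316 and 0.311 ± 0.538 CPM in adherent cells (SD, n = 3). The embryonic globin list gave 1 count in all 6 libraries. Of 10 megakaryocyte genes 5 were higher (5 adjusted over the list alone, median 2.22, camera adjusted p = 0.00551, adjusted p = 0.535 with an estimated correlation). That count was 8 without the adherent library of day 4, 8 by DESeq2 and 1 with a filter of at least 10 CPM in 3 libraries. Plek, a protein kinase C substrate found in platelets among other cells, was at 2.36 ± 0.35 log2. Clec1b, a platelet receptor, was at 2.30 ± 0.53, at low levels of 3.08 against 0.625 CPM. Of 14 mast cell and basophil genes 2 were higher (1 adjusted over the list alone, median 1.52, camera adjusted p = 0.0659), namely the protease genes Prss34 and Mcpt4. Prss34 had no count in adherent libraries and was at least 97.4-fold higher in suspension against a floor of 3 counts per library. Mcpt4, at 4.35 ± 1.28 log2 (adjusted p = 0.0263), had an adjusted p of 0.0962 without the suspension library of day 5 and of 0.0535 and 0.0593 without the adherent library of day 5 or 6. The count of higher mast cell genes was 1 without the suspension library of day 5 or the adherent library of day 5, and 4 without the adherent library of day 6. It was 4 by DESeq2 and 0 with a filter of at least 10 CPM in 3 libraries.

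Regulators of the transition from endothelial to blood cells were mostly higher in suspension. Of 22 tested, 15 were higher and 3 lower (15 and 3 adjusted over the list alone, median 1.31, camera adjusted p = 0.00145, adjusted p = 0.535 with an estimated correlation). The 3 lower genes were Meis1 at -3.06, Mecom at -2.93 and Hlf at -1.74 log2, which are also in the stem and progenitor list. The number lower was 1 without the suspension library of day 5 or the adherent library of day 5 or 6. Some of the higher genes are carried by blood cells in general, so the counts do not by themselves show a transition. Spi1 (PU.1), a transcription factor of myeloid cells, was at 2.66 ± 0.41 log2, Ptprc (CD45), carried by most blood cells, at 3.11 ± 0.43, and Cd44 at 1.45 ± 0.10. Gfi1, a repressor active when blood cells arise from endothelium, was at 9.43 ± 1.47 CPM in suspension and 1.29 ± 0.755 in adherent cells (SD, n = 3), with an adjusted p of 0.00401 from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Runx1 (ENSMUSG00000022952, mm10 chromosome 16, 92601466 to 92826149), the transcription factor required for that transition, was higher by a smaller ratio, at 108 ± 10.9 against 75.8 ± 2.63 CPM (SD, n = 3). Its log2 ratio of 0.50 ± 0.11 had an adjusted p of 0.00739, which became 0.0510 and 0.0651 without the suspension library of day 4 or of day 5. Haematopoietic stem and progenitor genes went both ways, 6 higher and 11 lower of 19 (6 and 11 adjusted over the list alone, median -1.74, camera adjusted p = 0.194). With a filter of at least 10 CPM in 3 libraries, which tests fewer genes, 1 was higher and 7 lower. Cd48 was at 1.93 ± 0.43 log2 and Cd34, which marks endothelial cells as well as progenitors, at -3.39 ± 0.58. The receptor gene Kit did not pass the test, at 10.8 ± 2.73 against 15.9 ± 5.38 CPM (SD, n = 3; adjusted p = 0.145 by edgeR). Of 14 Notch pathway genes 10 were lower and 2 higher (10 and 2 adjusted over the list alone, median -3.64, camera adjusted p = 0.00819, adjusted p = 0.535 with an estimated correlation). The number lower was 1 with a filter of at least 10 CPM in 3 libraries, which tests fewer genes. The Notch target Hes1 was at -3.61 ± 0.81 log2 and the receptor gene Notch1 at 0.73 ± 0.17. Of 10 receptors for the cytokines in the medium, 7 were lower and 2 higher (7 and 2 adjusted over the list alone, median -2.79, camera adjusted p = 0.0634).

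Cell cycle genes were higher in suspension by small ratios. Of 24 S phase genes 17 were higher and of 24 G2 and M phase genes 12 (17 and 12 adjusted over the list alone, medians 0.70 and 0.75), with camera adjusted p = 0.000157 and 0.000241 and adjusted p = 0.634 for both with an estimated correlation. With the collection day as a block, 19 G2 and M phase genes passed. The G2 and M phase count was 5, 4 and 6 without the suspension library of day 4, 5 or 6, 22 without the adherent library of day 4 and 5 without that of day 5. The S phase count was 11, 8 and 10 without the suspension library of day 4, 5 or 6, 10 without the adherent library of day 5, and 11 without globin and mitochondrial genes. Mki67, a protein of dividing cells, was at 266 ± 4.94 CPM in suspension and 96.5 ± 18.0 in adherent cells, and Top2a, a topoisomerase of dividing cells, at 281 ± 11.9 and 153 ± 52.1 (SD, n = 3). The adjusted p of Top2a, 0.0199 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, became 0.0639, 0.0867 and 0.0711 without the suspension library of day 4, 5 or 6 and 0.0728 without the adherent library of day 5. All 13 mitochondrially encoded genes were lower in suspension (13 adjusted over the list alone, median -2.23, camera adjusted p = 1.16e-05, adjusted p = 0.535 with an estimated correlation). Adherent libraries also had more reads assigned to no gene on the sense strand, 23.8% ± 0.416 against 16.7% ± 0.0551 (SD, n = 3). These include reads on the antisense strand of genes, and whether the others lie in introns or between genes cannot be told from the counts.

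Across all genes, 4044 of 14912 were higher and 4423 lower in suspension by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. That is 56.8% of genes, and 5403 of them had fitted ratios over 2. In 67.8% of genes the libraries of the fractions did not overlap, where chance gives 10%. Fraction was the leading axis of the data, with 86.4% of the variance in the top component against 6.4% in the next. With the collection day as a block 4074 and 4343 genes passed, with at least 10 CPM in 3 libraries 2365 and 2741, and in a test against a 2-fold difference 1308 and 2451. Of the genes named for the fractions, Cd93, Cd48, Spp1, Mcpt4, Top2a, Notch1, Runx1, Abca3, Hopx, Aqp1, Mecom and Hlf did not pass that last test (adjusted p from 0.0533 to 1). Nor did Cbfa2t3, Tal1, Lmo2 and Fli1 among the higher transition regulators (adjusted p from 0.0954 to 0.849). No more than 1 of the G2 and M phase genes and none of the S phase genes passed. The test against a 2-fold difference called 13 macrophage and 5 lysosome genes higher, 3 stem and progenitor genes higher and 7 lower, 1 mast cell, 1 epithelial and 1 Notch pathway gene higher, 1 transition regulator lower, and none of the cholesterol synthesis genes.

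**Figure D1:**
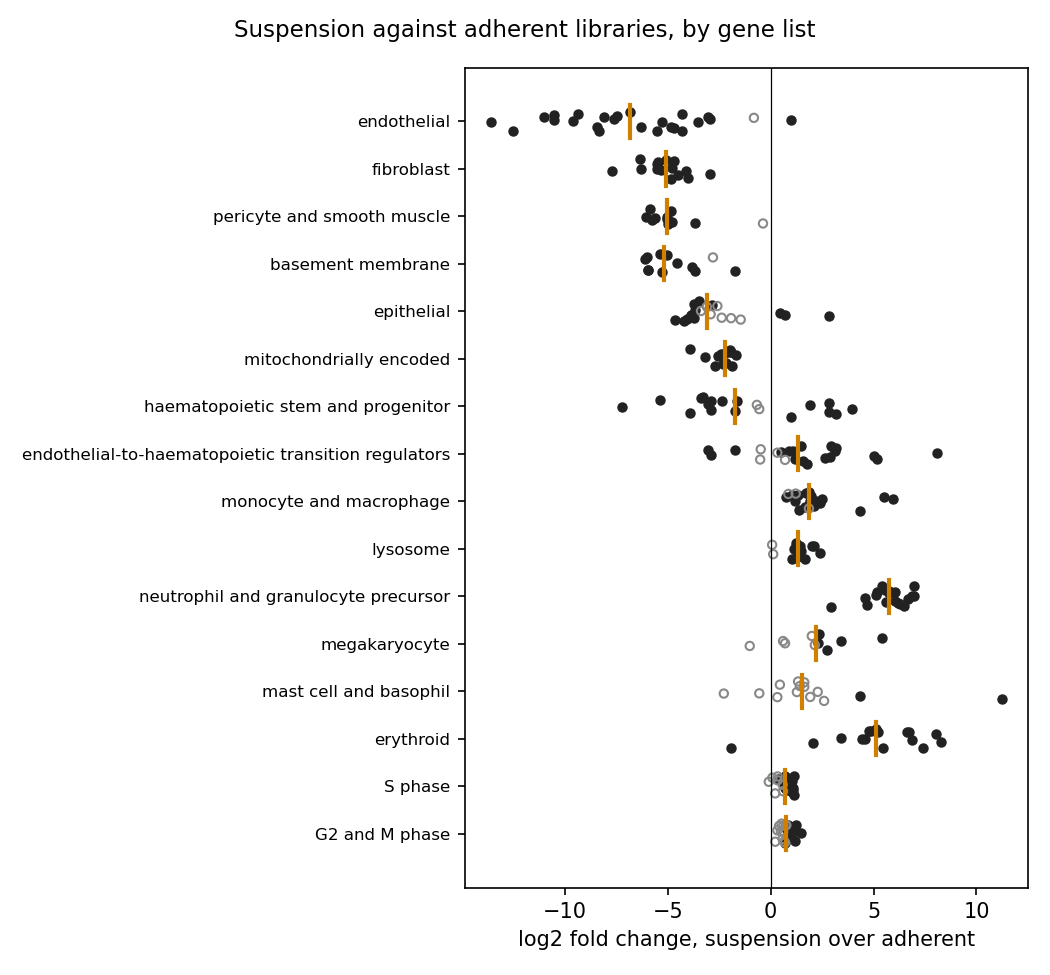
Log2 ratio of suspension to adherent libraries for the tested genes of 16 lists, 1 point per gene, filled where the gene passed edgeR's test, with the list median as a vertical bar. Medians run from -6.83 for endothelial to 5.75 for neutrophil and granulocyte precursor genes.

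The share of each library's gene counts taken by a list gives the same comparison without a model, although 3 libraries against 3 allow no p below 0.1. Neutrophil genes took 4.55% ± 2.44 of counts in suspension and 0.0939% ± 0.0518 in adherent cells (SD, n = 3, exact permutation p = 0.1, two-sided). Macrophage genes took 3.52% ± 0.233 and 1.12% ± 0.375 (exact permutation p = 0.1). Endothelial genes took 0.0320% ± 0.00404 in suspension, where Cd93 alone gave 89.3% of that share, and 0.191% ± 0.0881 in adherent cells, and fibroblast genes 0.0156% ± 0.00803, of which Fn1 gave 64.9%, and 0.349% ± 0.0583, of which it gave 25.7% (exact permutation p = 0.1 for both). Epithelial genes took 0.0286% ± 0.0147 and 0.128% ± 0.0664 (exact permutation p = 0.1), of which Napsa gave 39.5% in suspension and Sftpc 46.7% in adherent cells, erythroid genes 0.0189% ± 0.00943 and 0.00177% ± 0.000919 (exact permutation p = 0.1), of which Aqp1 gave 72.2% in adherent cells, and mitochondrially encoded genes 1.48% ± 0.134 and 8.20% ± 2.88 (exact permutation p = 0.1). Mast cell genes took 0.0352% ± 0.00565 and 0.0186% ± 0.0125 (exact permutation p = 0.2), megakaryocyte genes 0.162% ± 0.0298 and 0.110% ± 0.0369 (exact permutation p = 0.3), of which Pf4, which did not pass between the fractions (adjusted p = 0.130 by edgeR), gave 82.5% and 93.9%, and embryonic globins had an exact permutation p of 1. The libraries without a count of embryonic globins allow a share of up to 5.19e-06% to 8.23e-06%. By day, macrophage genes took 0.770% (95% Wilson interval 0.768 to 0.773), 1.08% (1.07 to 1.08) and 1.52% (1.51 to 1.52) of adherent counts, and mitochondrially encoded genes 11.4% (11.37 to 11.39), 7.44% (7.43 to 7.45) and 5.78% (5.77 to 5.78). With Benjamini-Hochberg adjustment over these 10 lists no share passed at 0.05, since the smallest p was 0.1.

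**Figure D2:**
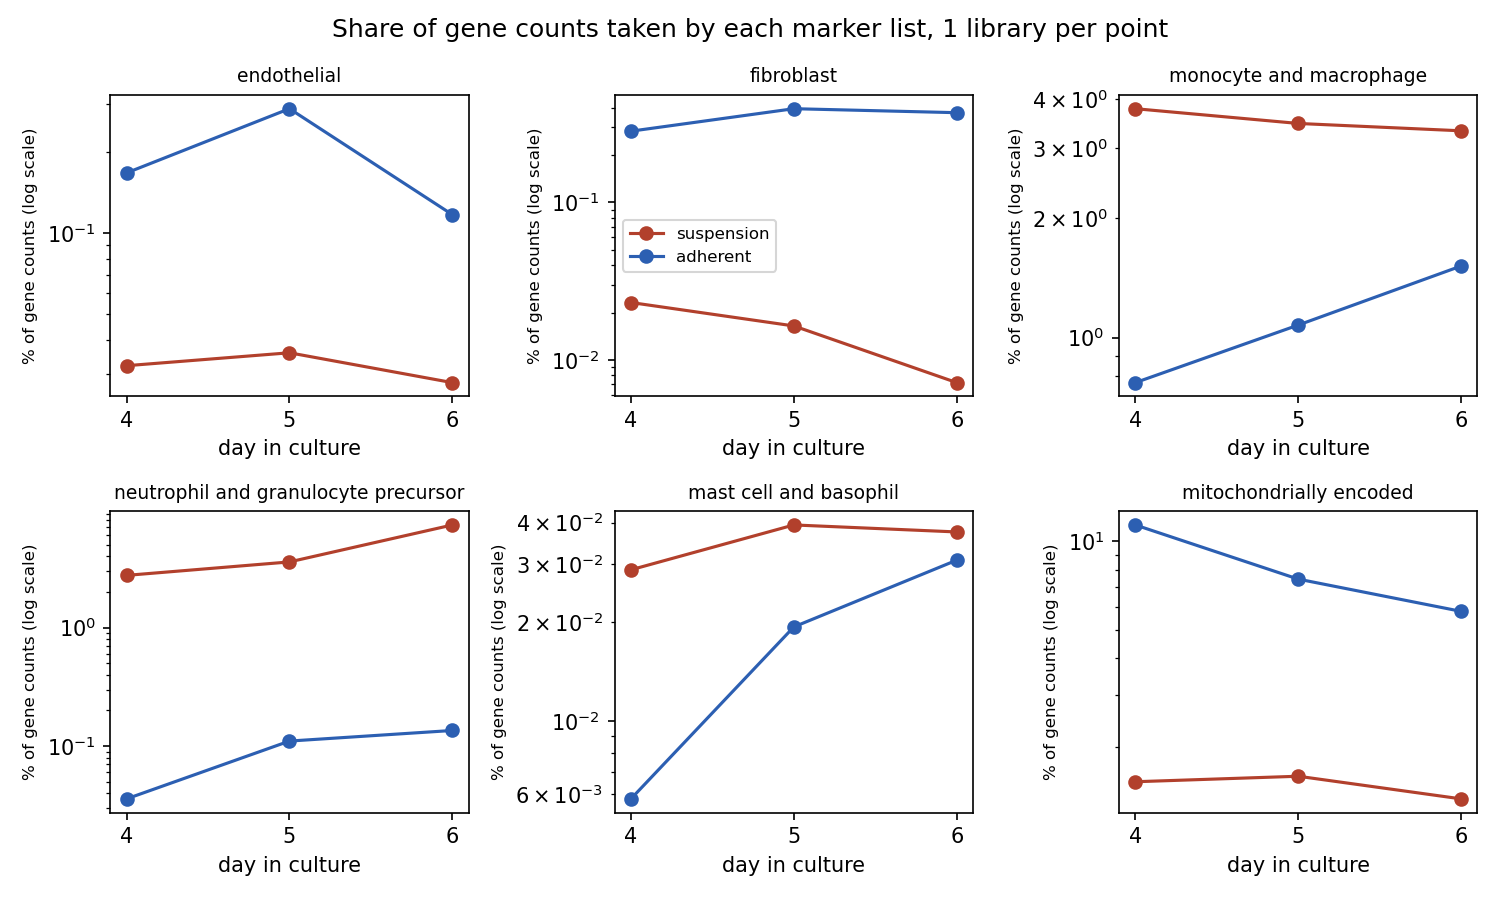
Percent of gene counts taken by 6 marker lists (log axis) against day in culture, 1 library per point, suspension and adherent as separate lines. Macrophage genes take 0.770%, 1.08% and 1.52% of adherent counts on days 4, 5 and 6, and mitochondrially encoded genes 11.4%, 7.44% and 5.78%.

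A day trend common to both fractions asked which genes changed with time in culture wherever the cells were. Slc40a1 (ferroportin, the iron exporter, ENSMUSG00000025993, mm10 chromosome 1, 45908068 to 45926523) and F630028O10Rik (ENSMUSG00000078122, chromosome X, 96239926 to 96243636) rose by this test. Slc40a1 was at 26.4, 48.8 and 80.9 CPM in suspension and at 7.36, 13.2 and 26.1 in adherent cells on days 4, 5 and 6, a slope of 0.86 ± 0.05 log2 per day. F630028O10Rik was named after its values were seen, at 35.02, 74.1 and 149 CPM in suspension and 1.22, 2.37 and 6.15 in adherent cells, a slope of 1.103 ± 0.063 log2 per day. Both had an adjusted p of 0.0459 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and no gene fell past the threshold, while 3036 of the 14912 had an unadjusted p under 0.05. DESeq2 called 684 rising and 720 falling. No gene passed without globin and mitochondrial genes, in a test of day 6 against day 4, or without the suspension library of day 4 or 5 or the adherent library of day 4 or 5, and in these fits between 2103 and 2990 genes had an unadjusted p under 0.05. Without the suspension library of day 6, 13 passed and without the adherent library of day 6, 7. For Slc40a1 the adjusted p was 0.142 and 0.171 without the suspension library of day 4 or 5, and 0.139, 0.231 and 0.0558 without the adherent library of day 4, 5 or 6. Its slope in these fits lay between 0.81 and 0.86 log2 per day. None of the other named genes passed by edgeR, while DESeq2 called S100a9 and Ptprc (adjusted p = 4.24e-06 and 0.00339), and their slopes in log2 per day were 0.55 for Ptprc, 0.48 for Spi1, 0.37 for Cd48, 0.99 for S100a9, 0.35 for Lyz2, 0.36 for Pf4, 1.33 for Cma1, 0.17 for Hbb-bs and 0.17 for Kit. They were -0.39 for Fn1, -1.02 for Sftpc, -0.21 for Top2a, -0.04 for Rbpj, 0.03 for Cd93, -0.38 for Cdh5, -0.31 for Pecam1, -0.09 for Runx1, -0.52 for Gfi1 and -0.55 for Cd34. Some of these hung on 1 library: Hbb-bs was at -2.15 without the suspension library of day 6, Cdh5 at 0.32 without the adherent library of day 6, Rbpj at 0.07 and 0.19 without the adherent library of day 4 or 6, Cd93 at -0.04, 0 and -0.11 without the suspension library of day 4 or 5 or the adherent library of day 4, and Kit at -0.01 and 0 without the suspension library of day 4 or 6. A common slope need not hold in both fractions. In suspension and adherent cells the slopes were 0.18 and 3.18 for Cma1 and -2.33 and 0.007 for Sftpc, while S100a9 rose in both, by 0.86 and 1.16.

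By list, camera called 7 lists rising and 9 falling in the common trend, none of them with an estimated correlation (adjusted p of 0.701 or more) and none by fry, which tests whether a list moves on balance 1 way. Cholesterol synthesis genes had a median of -0.41 log2 per day and a camera adjusted p of 5.84e-09 (adjusted p = 0.701 with an estimated correlation), with 0 of 15 genes falling over all genes by edgeR and 14 adjusted over the list alone. Of these 14 had an unadjusted p under 0.05, and DESeq2 called 11. G2 and M phase genes had a median of -0.29 (camera adjusted p = 3.33e-08, adjusted p = 0.701 with an estimated correlation), with 0 of 24 falling over all genes by edgeR and 9 adjusted over the list alone. Of these 15 had an unadjusted p under 0.05, and DESeq2 called 8. Neutrophil genes had a median of 0.63 (camera adjusted p = 4.79e-06, adjusted p = 0.701 with an estimated correlation), with 0 of 19 rising over all genes by edgeR and 8 adjusted over the list alone. Of these 9 had an unadjusted p under 0.05, and DESeq2 called 7. By fraction, median slopes in suspension and adherent cells were -0.23 and -0.53 for cholesterol synthesis and 0.79 and 1.16 for neutrophil genes. For G2 and M phase genes they were -0.09 and -0.50, so that fall was mainly one of adherent cells. By edgeR 22 of the 24 passed over all genes in adherent cells and 0 in suspension.

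By the slope of adherent cells in a joint fit of all 6 libraries, macrophage and lysosome genes rose over the days and cell cycle and cholesterol synthesis genes fell. Of 23 macrophage genes 14 rose by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (21 adjusted over the list alone), with a median slope of 0.62 log2 per day (camera adjusted p = 2.08e-07, adjusted p = 0.550 with an estimated correlation). Lyz2 was at 1526, 2190 and 4181 CPM on days 4, 5 and 6, the complement gene C1qb at 372, 475 and 1108, and the macrophage protein gene Cd68 at 155, 196 and 441. Without the suspension library of day 4, 5 or 6 the count was 5 each time, and without the adherent library of day 4 or 6 it was 7 and 3. Of 16 lysosome genes 13 rose (16 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 2.85e-07, adjusted p = 0.550 with an estimated correlation). The lysosomal protease gene Ctsd went from 1317 to 3102 CPM. The lysosome count was 4, 4 and 5 without the suspension library of day 4, 5 or 6 and 1 without the adherent library of day 4 or of day 6. Markers of other blood cells moved in the same libraries. Of 19 neutrophil genes 5 rose (6 adjusted over the list alone, median 1.16, camera adjusted p = 0.00144, adjusted p = 0.854 with an estimated correlation) and of 14 mast cell genes 3 (8 adjusted over the list alone, median 1.90, camera adjusted p = 0.00960, adjusted p = 0.854 with an estimated correlation). The mast cell tryptase gene Tpsb2 was at 0, 18.8 and 72.3 CPM on days 4, 5 and 6. The neutrophil count was 0 without any 1 suspension library, and 1, 14 and 12 without the adherent library of day 4, 5 or 6. It was 12 by DESeq2 and 10 without a filter on low counts. The mast cell count was 0 without any 1 suspension library, and 9 and 5 without the adherent library of day 5 or 6. It was 8 by DESeq2, 8 without a filter on low counts and 5 with thinned counts.

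Among 24 G2 and M phase genes 22 fell in adherent cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (23 adjusted over the list alone), with a median slope of -0.50 log2 per day (camera adjusted p = 2.23e-15, adjusted p = 0.550 with an estimated correlation). Top2a was at 211, 140 and 109 CPM on days 4, 5 and 6 and Ube2c, which marks mitotic proteins for breakdown, at 199, 160 and 91.4. The count was 12, 11 and 12 without the suspension library of day 4, 5 or 6, and 2 and 1 without the adherent library of day 4 or 6. Of 24 S phase genes 13 fell (19 adjusted over the list alone, median -0.31, camera adjusted p = 1.03e-11, adjusted p = 0.550 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, was at 70.8, 38.2 and 27.8 CPM. The S phase count was 3, 2 and 3 without the suspension library of day 4, 5 or 6, and 0 and 2 without the adherent library of day 4 or 6. Of 15 cholesterol synthesis genes 14 fell (14 adjusted over the list alone, median -0.53, camera adjusted p = 3.34e-10, adjusted p = 0.550 with an estimated correlation). The cholesterol count was 6 without any 1 suspension library, and 1 and 0 without the adherent library of day 4 or 6. Of 13 mitochondrially encoded genes 6 fell (11 adjusted over the list alone, median -0.45, camera adjusted p = 4.84e-08, adjusted p = 0.550 with an estimated correlation). That count was 2, 0 and 3 without the suspension library of day 4, 5 or 6 and 0 without the adherent library of day 4 or of day 6. Of 15 fibroblast genes 4 rose (6 adjusted over the list alone, median 0.32, camera adjusted p = 0.217), and 1 without the adherent library of day 6. Eln (elastin) was at 3.53, 13.8 and 93.8 CPM and Tcf21, a transcription factor of lung mesenchyme, at 3.62, 7.73 and 45.3. Of 25 endothelial genes 1, the caveolin gene Cav1, fell (1 adjusted over the list alone, median -0.30, camera adjusted p = 0.00878, adjusted p = 0.854 with an estimated correlation). That count was 0 without any 1 suspension library, 14, 6 and 0 without the adherent library of day 4, 5 or 6.

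Over all genes, 1156 rose and 525 fell in adherent cells. With globin and mitochondrial genes left out 926 rose and 665 fell, and DESeq2 called 1474 rising and 870 falling. Without the suspension library of day 4, 5 or 6 the counts were 339 and 127, 300 and 108, and 348 and 134. Without the adherent library of day 4, 5 or 6 they were 234 and 122, 1903 and 999, and 218 and 70. Leaving out a suspension library takes away no adherent value, so those lower counts came through the estimate of the spread, the filter or the scaling.

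In suspension, 14 genes rose and 60 fell over the days. Among epithelial genes 3 of 19 fell over all genes and 14 adjusted over the list alone, with a median of -1.94 log2 per day (camera adjusted p = 4.26e-09, adjusted p = 0.647 with an estimated correlation). The keratin genes Krt8, Krt18 and Krt19 were these 3, and Krt18 was at 27.2, 4.77 and 1.19 CPM on days 4, 5 and 6. Other lists of attached cells fell with them by camera, namely pericyte and smooth muscle genes (median -1.46, 1 of 11 over all genes and 8 adjusted over the list alone, camera adjusted p = 6.54e-06), basement membrane genes (median -1.05, 1 of 12 and 4, camera adjusted p = 0.000103) and fibroblast genes (median -0.97, 0 of 15 by edgeR, 8 at an unadjusted p under 0.05, 4 by DESeq2 and 6 adjusted over the list alone, camera adjusted p = 0.000103), each with an adjusted p of 0.647 with an estimated correlation. Neutrophil genes that rose were Ngp, from 1501 to 5072 CPM, and Mmp9, from 21.1 to 96.1 CPM, so 2 of 19 over all genes and 11 adjusted over the list alone (median 0.79, camera adjusted p = 0.000103, adjusted p = 0.763 with an estimated correlation). The total of 74 was 0 without the suspension library of day 4 or of day 6 (1119 of 15428 and 713 of 15469 genes at an unadjusted p under 0.05), 509, 544 and 543 without the adherent library of day 4, 5 or 6, and 768 by DESeq2. The 713 genes are no more than the share of 0.05 that chance gives. Leaving out an adherent library takes away no suspension value, so the counts from 509 to 544 came through the estimate of the spread, the filter or the scaling.

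The test of the difference between the slopes asked whether the fractions changed differently with time. It called 77 genes, 8 with the higher slope in suspension and 69 with the higher slope in adherent cells, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By camera, macrophage genes had the higher slope in adherent cells (median difference -0.61, 0 of 23 genes over all genes by edgeR, 14 at an unadjusted p under 0.05, 10 by DESeq2 and 13 adjusted over the list alone, camera adjusted p = 4.76e-05, adjusted p = 0.616 with an estimated correlation). Lysosome genes did too (median -0.54, 0 of 16 over all genes by edgeR, 16 at an unadjusted p under 0.05, 14 by DESeq2 and 16 adjusted over the list alone, camera adjusted p = 1.54e-07, adjusted p = 0.548 with an estimated correlation), and they were called by fry, with an adjusted p of 0.00735. The macrophage difference was not particular to that list, since fibroblast, pericyte and smooth muscle, and epithelial genes had medians of -1.16, -1.19 and -1.25 (camera adjusted p = 5.12e-05, 0.00116 and 0.000850, adjusted p = 0.616, 0.616 and 0.659 with an estimated correlation). For these 3 lists 0 genes passed over all genes by edgeR, 10, 8 and 12 had an unadjusted p under 0.05, DESeq2 called 7, 4 and 9, and 9, 7 and 9 passed adjusted over the list alone. Mitochondrially encoded genes went the other way (median 0.39, 0 of 13 over all genes by edgeR, 10 at an unadjusted p under 0.05, 5 by DESeq2 and 9 adjusted over the list alone, camera adjusted p = 1.18e-08, adjusted p = 0.548 with an estimated correlation). G2 and M phase genes had the higher slope in suspension (median 0.43, 0 of 24 over all genes by edgeR, 22 at an unadjusted p under 0.05, 13 by DESeq2 and 21 adjusted over the list alone, camera adjusted p = 1.59e-14, adjusted p = 0.548 with an estimated correlation). Ms4a8a, a membrane protein gene, was at 151, 151 and 142 CPM in suspension and at 3.14, 10.5 and 41.2 in adherent cells, with an adjusted p of 0.0332. The cytokine gene Il18 was at 241, 216 and 185 CPM in suspension and at 10.8, 21.9 and 49.3 in adherent cells, with an adjusted p of 0.0485. Neither passed without any 1 suspension library (adjusted p from 0.0789 to 0.700). The slope differences in those fits were from -1.96 to -1.82 log2 per day for Ms4a8a and from -1.32 to -1.21 for Il18. The total of 77 was 0 without the suspension library of day 4, 5 or 6 (1496 of 15428, 2469 of 15441 and 1044 of 15469 genes at an unadjusted p under 0.05, where chance gives a share of 0.05) and 859 without the adherent library of day 5. It was also 0 without globin and mitochondrial genes, where 2866 genes had an unadjusted p under 0.05, and 956 by DESeq2.

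**Figure D3:**
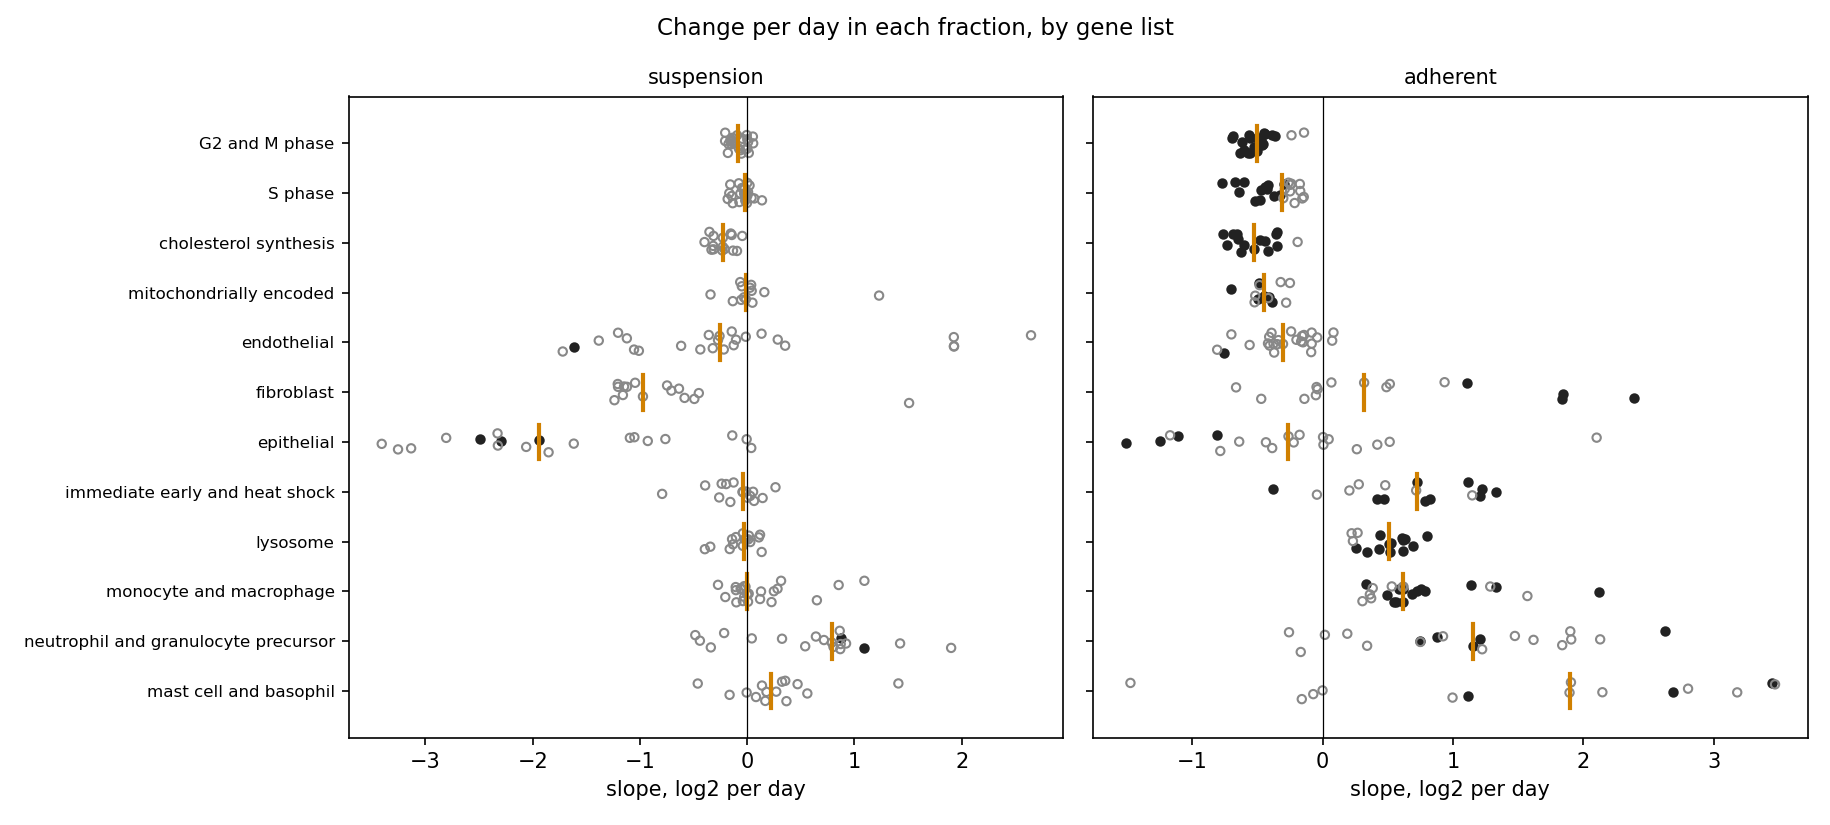
Slope in log2 per day for the tested genes of 12 lists, suspension on the left and adherent on the right, 1 point per gene, filled where the gene passed edgeR's test, with the list median as a vertical bar. In adherent cells medians run from -0.53 for cholesterol synthesis to 1.90 for mast cell and basophil genes.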

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

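The test of the slope difference was planned, while the tests of explanations and the counts of other splits and day orders in this part were chosen only after the results were seen.

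Macrophage genes rose over the days in adherent libraries, with 14 of 23 past the threshold, among them Lyz2 at 4181 CPM on day 6 but not Spp1 at 4810 CPM (adjusted p = 0.117), and none of the 23 listed genes is in another list. Carry-over of suspension cells as a whole, or of their free RNA, would bring all genes of suspension cells in 1 ratio. Adherent levels as a percent of suspension levels (median over genes with at least 5 CPM there) were at the least 8.196 times as high for macrophage as for neutrophil genes on a day. On days 4, 5 and 6 they were 18.2%, 21.1% and 38.3% for macrophage genes and 0.697%, 2.58% and 1.48% for neutrophil genes. For mast cell genes they were 0.981%, 24.7% and 75.2%, over 7, 10 and 7 genes that reached the CPM limit. Single mast cell genes differed widely, with quartiles of 0.147% and 92.7% on day 4, 20.6% and 67.3% on day 5 and 66.2% and 76.7% on day 6. The values of the macrophage and neutrophil lists argue only against carry-over in 1 ratio for all genes, and carry-over of only some suspension cells was not tested. Counts set free by the fall of mitochondrial genes do not account for the rise, since 12 macrophage genes passed without globin and mitochondrial genes, against 14 with them. A rising share of macrophages among the collected cells, which the sort for VE-cadherin should remove, free RNA of attached macrophages and a change in the cells with time in culture stay open, as none was tested and the tables have no cell axis.

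Mitochondrially encoded genes were higher in adherent than in suspension libraries and fell in adherent ones over the days. Damaged cells that lose cytoplasmic RNA keep mitochondrial and nuclear RNA, so damage that lessened over the days would lower both, but the median slope of the nuclear RNAs Malat1, Neat1 and Kcnq1ot1 in adherent cells was 0.358 log2 per day. Against that, reads assigned to no gene on the sense strand fell with the mitochondrial genes, from 24.22% on day 4 to 23.60% and 23.43%. So did unmapped reads (8.04%, 6.40% and 5.90%) and reads mapped to several places (22.61%, 20.25% and 18.67%), so lessening damage and a change in the cells with time cannot be told apart. A test on the 3 RNAs only, which had argued against damage, was replaced by one that also takes reads assigned to no gene. Between the fractions the median log2 ratio of the 3 RNAs was -0.039, while reads assigned to no gene on the sense strand were 1.421 times as frequent in adherent libraries. Only adherent cells went through the enzyme and the sort, so damage and a difference between the cell types cannot be told apart there.

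Cell cycle genes fell in adherent libraries over the days. A falling share of endothelial cells would lower endothelial genes by at least as much, but from day 4 to day 5 the median ratio of endothelial genes was 1.693, with 24 of 25 higher, while that of G2 and M phase genes was 0.687. From day 5 to day 6 the ratios were 0.3876 and 0.726, so for that step a falling endothelial share may be part of the cause. Fewer counts for mitochondrial genes would raise the shares of other genes, so they could not give this fall and a test of it decides nothing. For the record, 22 G2 and M phase genes passed with and without globin and mitochondrial genes. This test of single steps replaced one on the slopes of endothelial and fibroblast genes, set after the slopes were seen, which had argued by a narrow margin against a dilution of both cell types, and slower division with time in culture stays open as untested.

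The slope in suspension minus that in adherent cells differed from 0 by the interaction test for 5 named genes. It was 0.91 log2 per day for Gas7, 0.88 for Nudt4, 0.90 for Glipr2, -1.91 for Ms4a8a and -1.28 for Il18. Adjusted p-values lay between 0.0332 and 0.0485 by edgeR, and all 5 genes had an adjusted p of 0.700 without the suspension library of day 6. These were 0.112 to 0.238 without that of day 4 and 0.0789 to 0.0956 without that of day 5, for Gas7 and Nudt4 0.0662 and 0.0663 without the adherent library of day 4, and for Gas7, Nudt4 and Glipr2 0.0609, 0.0863 and 0.0816 without that of day 6. Without globin and mitochondrial genes they were 0.0507 to 0.0585. The differences in that fit were 0.93 for Gas7, 0.90 for Nudt4, 0.92 for Glipr2, -1.89 for Ms4a8a and -1.26 for Il18. With reads on either strand Gas7 had a difference of 0.75 and an adjusted p of 0.05035. Data outside the gene counts gave signals too. Reads on the antisense strand of genes made up 6.90% of stranded gene reads in suspension and 6.387% in adherent libraries, reads mapped to several places 14.75% and 20.51% of all reads, and reads assigned to no gene on the sense strand 16.72% and 23.75%.

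The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05, and 1 split, the real one, gave 8467 genes while the highest other gave 0. Every other split mixes the fractions, so their difference enters the spread, and the 0 gives no chance level for the 8467. The days allow 18 orders that are not mirror images of each other, again too few for a share under 0.05. For the common trend 1 order, the real one, gave 2 genes and the highest other 0. For the slope difference 2 orders gave 77 genes or more, the highest other being 1612 with the adherent days reversed, which turns the difference of the slopes into their sum. That points to a structure of the libraries by day, which adherent changes, at 1681 genes for their slope, can give without any shared by the fractions. For the suspension slope 2 orders gave 74, the highest other being 74, and for the adherent slope 2 gave 1681, the highest other being 1681. In both cases the other order reversed the adherent days, which leaves the suspension slope as it was and turns only the sign of the adherent slope.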

How the results depend on the processing

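Of the alternatives in this part, the list tests on the slopes and on the slope difference and the counts for Y-linked and X-inactivation genes were added only after the data were seen. Among 189 alternative values of main results 136 kept their direction and their side of the threshold or stayed within 1.5 times, and 53 moved. No named gene reversed, and of 972 alternative values of named genes 904 stayed the same, 56 lost and 2 gained their call, and 10 that had not passed changed sign. Of 535 alternative counts of list members 405 stayed within 1.5 times. Leaving out a library leaves 3 residual degrees of freedom or fewer. In the slope fits it leaves fewer than the 2 of the full fit, so changed counts there may reflect that loss and not the library.

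A filter of at least 10 CPM in 3 libraries tests fewer genes and gave 2365 genes higher in suspension and 2741 higher in adherent cells, and a test against a 2-fold difference gave 1308 and 2451. Without a filter on low counts the common trend gave 66 genes, the slope difference 1006, the suspension slope 809, and the adherent slope 1738 rising and 908 falling. DESeq2 gave 1404, 956 and 768 for the first 3 of these and 870 falling in adherent cells. Without globin and mitochondrial genes the common trend and the slope difference gave 0 genes each by edgeR (2990 and 2866 at an unadjusted p under 0.05), and day 6 against day 4 gave 0 (2310). The cause was not tested.

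With each library left out in turn the common trend ranged from 0 to 13 genes, the slope difference from 0 to 859, the suspension slope from 0 to 544, rising genes in adherent cells from 218 to 1903 and falling ones from 70 to 999. Where edgeR gave 0 genes, between 1044 and 2990 had an unadjusted p under 0.05 in the trend and the slope difference, and 713 and 1119 in the suspension slope. Of these, 713 of 15469 genes is no more than the share of 0.05 that chance gives. The embryonic globin share rests on 1 count, and its difference ranged from 0 to 1.131e-06%. With an estimated correlation 0 lists were called in each of the fraction contrast, the common trend, the slope difference, the suspension slope and the adherent slope, against 17, 16, 13, 10 and 14 with the preset one. Limma's fry called 22 of 34 lists in the fraction contrast, 0 in the common trend, 3 in the slope difference, 0 in the suspension slope and 5 in the adherent slope. Depth limits statements on genes under about 0.0756 CPM, the level of 3 counts in the smallest library.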

Other observations

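The list tests on slopes in this part were chosen only after the data were seen, and the contrast of the fractions was planned.

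Genes of lung capillary endothelium were mostly lower in suspension. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 8 of 11 lung capillary genes were lower and 2 higher (8 and 2 adjusted over the list alone, median log2 ratio -4.76, camera adjusted p = 0.0369, adjusted p = 0.549 with an estimated correlation), the higher ones being Lpl, which encodes lipoprotein lipase, and Hpgd. Of 12 arterial genes 7 were lower and 2 higher (7 and 2 adjusted over the list alone, median -2.99, camera adjusted p = 0.128), of 6 venous genes 3 and 3 (3 and 3 adjusted over the list alone, median -1.23, camera adjusted p = 0.727), and of 7 lymphatic genes 4 and 1 (5 and 1 adjusted over the list alone, median -3.81, camera adjusted p = 0.109). The venous list holds Vwf, a clotting protein that platelets also carry, at 2.97 log2. Both tested mesothelial genes and 2 of 3 neural genes were lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.0954 for the neural list). Of 8 dendritic cell genes 6 were higher and 2 lower in suspension (6 and 2 adjusted over the list alone, median 3.21), which camera did not call (adjusted p = 0.0954), with H2-Ab1 at 5.28 and Cd74 at 2.80 log2. Lymphoid genes went both ways, with 3 of 5 B cell genes higher and 2 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.476) and 3 of 7 T, NK and innate lymphoid genes higher and 1 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.727). Fetal haematopoietic genes did so too, with 3 of 8 higher and 4 lower (3 and 4 adjusted over the list alone, median -1.31, camera adjusted p = 0.585), among them the fetal growth regulator Hmga2 at -3.94 and Lin28b at 3.61.

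Immediate early and heat shock genes, many of which respond within minutes to handling or signals, were lower in suspension for 6 of 16 and higher for 1 (6 and 0 adjusted over the list alone, median -0.92, camera adjusted p = 0.164). In adherent cells 9 rose over the days and 1, Hsp90aa1, fell (12 and 1 adjusted over the list alone, median 0.72 log2 per day, camera adjusted p = 0.00144, adjusted p = 0.854 with an estimated correlation). Fos was at 104, 445 and 663 CPM on days 4, 5 and 6 and Junb at 222, 482 and 610. The count of 9 was 1 without any 1 suspension library and 0 without the adherent library of day 4, and the fall of Hsp90aa1 was lost without any 1 suspension library or the adherent library of day 4 or 6. Cholesterol synthesis genes were higher in suspension for 7 of 15 (7 adjusted over the list alone, median 0.72, camera adjusted p = 0.0109, adjusted p = 0.659 with an estimated correlation). That count was 2, 1 and 4 without the suspension library of day 4, 5 or 6, 13, 2 and 4 without the adherent library of day 4, 5 or 6, 13 with the day as a block, and 0 in a test against a 2-fold difference. Glycolysis and hypoxia genes were higher for 8 of 16 and lower for 3 (8 and 3 adjusted over the list alone), with a median of 0.45, a mean of -0.17 and an upward camera direction (adjusted p = 0.362), and the secreted factor genes Vegfa and Adm were at -2.27 and -5.22. Interferon response genes were higher for 4 of 14 and lower for 3 (4 and 3 adjusted over the list alone), with a median of -0.31, a mean of -0.72 and an upward camera direction (adjusted p = 0.946). Inflammatory genes were higher for 5 of 15 and lower for 4 (5 and 4 adjusted over the list alone, median 0.56, camera adjusted p = 0.525). Of 5 Y-linked and X-inactivation genes 0 passed between the fractions by edgeR or DESeq2 (0 adjusted over the list alone), and 1 had an unadjusted p under 0.05. In the adherent slope 2 rose by edgeR and 2 by DESeq2 (3 adjusted over the list alone, camera adjusted p = 0.0771, fry adjusted p = 0.00131), and fry also called the slope difference (adjusted p = 0.00735). By edgeR the 2 became 0 without any 1 suspension library or without the adherent library of day 4 or 6, and 1 without globin and mitochondrial genes, with thinned counts or with DESeq2's size factors.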
